A study of Mus musculus with 3 samples.

How the data were processed

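The series holds 3 single-nucleus RNA libraries of mouse adipose nuclei, 1 per group: room temperature (RT), 4 days in the cold (CE4) and 7 days in the cold (CE7). Per the labels' protocols, tissue was homogenised, nuclei were stained with the DNA dye Hoechst and sorted on red fluorescence, and libraries were made with droplet 3' chemistry, version 3.1. The adipose depot and the number of animals per library are not given in the sources used here. The labels name the C57BL/6 strain and adipocytes as the cell type.

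The deposited values are counts of unique molecular identifiers (UMIs), which mark single captured RNA molecules, per gene and barcode, not normalized. Per the file headers, the authors made the counts with Cell Ranger 4. The submitters' processing notes name Cell Ranger, Seurat and the mouse build GRCm38.p6, without a version or role for each. The matrices list 6794880 barcodes per library and 26124 genes, so no barcode had been filtered out, and no cell annotation was used here. Of the gene identifiers, 26013 were found in GENCODE mouse release 21 (GRCm38), from which gene positions were taken. Repeated symbols (38 of them) were kept under their identifiers. Some members of the gene lists, such as Cox4i1, Cpt1b and Per3, are listed at 0 in every library, which is not read as absence of their RNA.

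Total UMIs were 60383240 in RT, 140834229 in CE4 and 170539025 in CE7. A barcode was kept when its UMIs reached the larger of 500 and 10% of the 99th percentile of the top barcodes (the order-of-magnitude rule of Cell Ranger), with at least 300 genes and at most 5% of UMIs from the 37 mitochondrial genes. This set the minimum at 500 UMIs in RT, 1464 in CE4 and 1235 in CE7. Likely doublets were removed by score (scrublet in scanpy 1.11.5), at 0.8% per 1000 barcodes, which took out 25.1%, 15.7% and 26.4% of the called barcodes. This share grows with the number of called barcodes, so droplets without a nucleus would raise it. With a minimum of 2000 UMIs the rule took out 2.8%, 14.2% and 18.6%. The main RT set held 2448 adipocyte-like barcodes of at least 2000 UMIs, against 3339 with that minimum. Counts were scaled to 10000 per barcode and log-transformed, and the 2000 most variable genes were reduced to 30 principal components. Barcodes were then joined by 15 nearest neighbours and clustered by the Leiden method at resolution 0.5 (igraph 0.11.9), with no integration of libraries, because library and condition are the same here.

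Clusters were named from 13 marker lists fixed before the data were examined, when at least 3 markers of a class other than adipocytes were among the cluster's 100 leading genes that were at least 2-fold above the other clusters, and no second class had more than 50% as many. A cluster with 3 or more mitochondrial or haemoglobin genes among its 20 leading genes was left unnamed. That last rule was chosen after seeing the data. Remaining clusters, in a sort for adipocyte nuclei, were called adipocyte-like when at least 3 adipocyte markers were detected in them and their 10 leading genes held no more markers of another class than of adipocytes. Every cluster met the first condition, so adipocyte-like is in effect the class of clusters that no other condition took. A shallow cluster without an adipocyte marker among those 10 genes was left unnamed.

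For each library the UMIs of all adipocyte-like barcodes were summed and scaled to a common library total, as counts per standard total (CPM). With 1 library per group no test across samples exists. Ratios carry an exact (Clopper-Pearson) conditional binomial 95% interval that covers counting error only, and shares of barcodes carry the exact binomial one. These intervals say nothing about variation between animals. A count of 0 was set to 3 in a ratio, which is then a bound. Genes with at least 100 UMIs in either library and a fold of at least 2 whose interval excluded 1 were counted, as a description of the libraries. The medians of 19 gene lists fixed before the data were examined were taken over members with at least 30 UMIs in the libraries compared. Each median was set against 10000 random lists matched on mean expression in 20 bins, and its counting interval came from 1000 Poisson draws. The lists were the thermogenic program, creatine cycling, calcium cycling, triglyceride lipolysis and re-esterification, de novo lipogenesis, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, glucose uptake and glycolysis, branched-chain amino acid catabolism, white adipocyte and adipokine, beta-adrenergic and cAMP signalling, immediate early and heat shock, integrated stress and unfolded protein response, angiogenic and matrix, circadian clock, cold-inducible RNA binding, depot and developmental, sex-linked and cell cycle genes.

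Genes were named in the text by a rule fixed beforehand. For each cold library against RT these were 13 genes chosen for their function, the 8 highest and 8 lowest of the 2-fold genes, ranked by the interval bound nearest to 0, and up to 3 of the 2-fold members of each list. For CE7 against CE4 they were the 5 highest and 5 lowest. For the comparison by Ucp1 within the cold libraries they were also the 5 highest and 5 lowest. These were ranked by the smallest absolute log2 ratio over the libraries, among genes with the same direction in each. A few other members of the lists are named where a count is described, and these were chosen after their values were seen.

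Shares of barcodes with Ucp1 were compared after each barcode had been thinned at random to 1000 UMIs. The other named or partly named classes gave the background. For the comparison within a library, thinned barcodes with at least 2 Ucp1 UMIs (Ucp1-high) were set against those with 0 (Ucp1-negative), with Ucp1 left out of the totals. Only genes for which at least 3 UMIs would fall in the Ucp1-high barcodes at the level of all barcodes were measured there, a limit chosen after seeing the data. Added after seeing the data were 10000 matched random lists for this comparison, and the comparison of barcodes with at least 1 Ucp1 UMI against those without, thinned to 500 UMIs, in adipocyte-like barcodes and in uncalled droplets of the peak. For the overlap of the 2 cold comparisons, 100 sets of libraries were simulated from the RT profile with no difference. The ratio and counting steps were tested on simulated libraries with 200 changed genes. For CE4 over RT (11721 genes) 44.8% of genes made 2-fold different and 100.0% of those made 3-fold or 6-fold different were counted, with 0 unchanged genes counted. For CE7 over RT (11802 genes) these shares were 46.3% and 100.0%, and for CE7 over CE4 (11565 genes) 49.3% and 100.0%, again with 0 unchanged genes.

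Alternatives fixed beforehand were a UMI minimum of 500 or of 2000, at most 1% mitochondrial UMIs, no doublets removed, Leiden resolution 1.0, median-of-ratios size factors, the mean of per-barcode CPM, removal of 10% of UMIs in proportion to the profile of barcodes of at most 50 UMIs, all classes together, count minimums of 30 and 300, thinning to 500 or 2000 UMIs, and other Ucp1 minimums. Removal of the profile of the droplet peak described below from barcodes of at least 2000 UMIs, alone and with median-of-ratios size factors, was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.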

Results

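Nuclei from mouse adipose tissue were profiled at room temperature (RT) and after 4 (CE4) or 7 (CE7) days in the cold, with 1 library per group, so no difference below has a replicate check. The series' title gives its purpose as telling apart adipocytes that use UCP1, the mitochondrial protein that turns the proton gradient into heat, from those that use futile metabolic cycles. The nuclei came from mice in which a red nuclear label marks adipocytes, and they were sorted on that label. Barcode calling kept 23482 barcodes in RT, 16536 in CE4 and 24296 in CE7, with medians of 693, 3825 and 2938 UMIs per barcode.

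Adipocyte-like clusters held 96.9% of RT barcodes (95% counting interval 96.7 to 97.1), 97.0% of CE4 (96.7 to 97.2) and 72.9% of CE7 (72.3 to 73.4). Macrophage-like barcodes made up 0.18% (0.13 to 0.24), 0.52% (0.42 to 0.64) and 0.33% (0.26 to 0.41), in nuclei sorted for the adipocyte label. A cluster with markers of both fibro-adipogenic progenitors and endothelium held 0.89%, 1.57% and 0.94%. The cluster led by haemoglobin and mitochondrial genes, kept out of every class, held 2.02% of RT, 0.93% of CE4 and 25.9% of CE7. Each library also had a peak of droplets around a fixed UMI number below its nuclei, at 473 UMIs in RT, 750 in CE4 and 1059 in CE7. The minimums of RT (500 UMIs, peak 398 to 562) and CE7 (1235, peak 891 to 1259) lay inside that peak, so many RT barcodes and part of those of CE7 may hold no nucleus. In CE7 the haemoglobin and mitochondrial cluster had a median of 1336 UMIs, near that minimum, which limits both its share and the adipocyte-like one, and values from barcodes of at least 2000 UMIs are given beside the main ones where they move a named result by over 1.5 times. At that minimum 3399, 15225 and 18952 barcodes were kept, of which 98.23%, 98.25% and 98.86% were adipocyte-like. At resolution 1.0, 12926 of the 22748 adipocyte-like RT barcodes lay in a cluster with an RT median of 566 UMIs, near the RT peak. Xlr5a, Lrp1b, Grik1 and Chl1 were among its 10 leading genes and among those of the haemoglobin and mitochondrial cluster. Droplets without a nucleus may thus count as adipocyte-like in RT, and the RT and CE7 shares cannot be compared as purity.

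**Figure D1:**
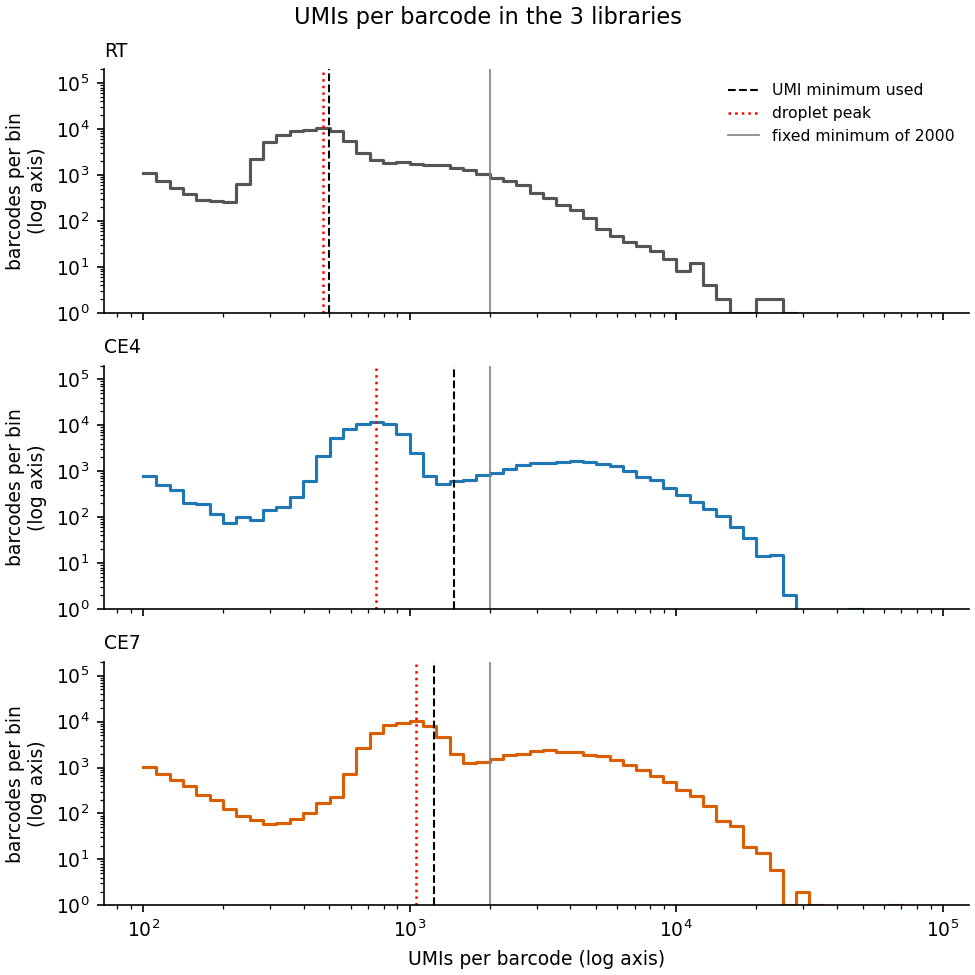
UMIs per barcode (horizontal log axis) against the number of barcodes per bin (vertical log axis) in RT, CE4 and CE7, from 100 UMIs up, with 1 CE7 barcode of 259652 UMIs beyond the axis. The dashed line is the UMI minimum used (500, 1464 and 1235), the dotted line the droplet peak (473, 750 and 1059) and the grey line the fixed minimum of 2000, and the minimum used falls within the peak in RT and at its upper edge in CE7.

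The adipocyte-like class of RT lay mostly in cluster 0 (20881 of 22757 barcodes). Most of it lay in clusters 2, 5 and 1 in CE4 (7027, 5444 and 3277 of 16038) and in CE7 (7277, 4874 and 5007 of 17703). Because cluster 0 is nearly a single library it may be that library and not a type of cell, so only the whole class was compared. Its UMIs summed to 24524140 in RT, 70586030 in CE4 and 74594983 in CE7.

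After 4 days in the cold, genes of heat production and fat burning were higher in adipocyte-like barcodes than in those of RT. Genes of fat synthesis and white-fat identity were lower. Many of the RT barcodes may hold no nucleus, as described above. Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452 in GRCm38) stood at 161 CPM (UMIs scaled to a common library total) in CE4 and 4.32 in RT, 37.2-fold higher, with a log2 ratio of 5.22 (4.94 to 5.51). The droplets of the peak held it at 210 CPM in CE4 and 3.91 in RT, so free RNA may be part of these values. Fabp3, a carrier of fatty acids, was at 13.2 against 0.20 CPM, and Cox7a1, a heart and brown-fat subunit of cytochrome oxidase, at 15.6 against 0.41. The bicarbonate cotransporter gene Slc4a4 (chromosome 5, 88886818 to 89239653) rested on many more molecules and was 15.1-fold higher, at 1082 against 71.6 CPM. Gk (chromosome X, 85701937 to 85776819), which codes for the glycerol kinase that lets an adipocyte reuse glycerol, was 9.15-fold higher, at 334 against 36.5 CPM.

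Of the 23 measured thermogenic genes, 19 were at least 2-fold higher in CE4 than in RT and 0 lower, and the list's median log2 ratio of 1.89 lay above all random lists (percentile 100). Fatty acid oxidation had a median of 1.21 (percentile 100), with 9 of 17 members at least 2-fold higher and 0 lower. Among its members, Ppara, the nuclear receptor that drives this pathway, was at 514 against 139 CPM, and Etfdh and Acaa2 had log2 ratios of 1.78 (1.70 to 1.87) and 1.75 (1.65 to 1.86). Nuclear-encoded oxidative phosphorylation had a median of 0.63 (percentile 100) and 4 of 23 members at least 2-fold higher, with Cox8b at a log2 ratio of 2.84 (2.55 to 3.14), or 3.48 at 2000 UMIs. Its members Cox7a1 and Cox8b, and Ppara and Cpt1b of the fatty acid oxidation list, are also in the thermogenic list. These lists therefore partly count the same genes. In the glucose list, with a median of 0.16 (percentile 77.1), Pdk4, which holds pyruvate back from oxidation, was 10.3-fold higher and Ldhb 5.93-fold higher, while the insulin-responsive glucose carrier Slc2a4 was at 91.6 against 211 CPM.

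De novo lipogenesis was lower in CE4, with a median of -0.73 (percentile 0.00) and 3 of 16 members at least 2-fold lower. These were Srebf1, a master regulator of the pathway, at 249 against 646 CPM, the mitochondrial citrate carrier Slc25a1 at 195 against 490, and Thrsp at 1134 against 2338. Fasn (fatty acid synthase, chromosome 11, 120805846 to 120824547) was at 728 against 1455 CPM, and Acaca had a log2 ratio of -0.43 (-0.43 to -0.42). White adipocyte and adipokine genes had a median of -0.65 (percentile 0.01), with 4 of 13 at least 2-fold lower. Cfd, the secreted protease adipsin, was 4.54-fold lower, the amino acid carrier Slc7a10 3.39-fold lower, and Igf1 and Lep (leptin) had log2 ratios of -1.09 (-1.12 to -1.06) and -1.07 (-1.13 to -1.01), while Adipoq (adiponectin) was at -0.40 (-0.46 to -0.34).

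The futile-cycle lists lay nearer to 0 than the thermogenic one. Creatine cycling had 6 measured genes and a median of -1.01 (percentile 4.56), which turned to 0.31 (percentile 80.6) in barcodes of at least 2000 UMIs, so these libraries give it no direction. Its members were rare: Ckb (creatine kinase B, chromosome 12, 111669361 to 111672338) had 49 UMIs in RT and 49 in CE4, a log2 ratio of -1.53 (-2.13 to -0.92) that was -0.82 at 2000 UMIs. Alpl, the phosphatase proposed to act on phosphocreatine, was at 6.32 against 17.6 CPM, and its log2 ratio of -1.48 became -0.47 at 2000 UMIs, which ended the 2-fold difference. The creatine carrier gene Slc6a8 was higher at 1.45 (0.61 to 2.40) from 13 UMIs in RT. Calcium cycling had a median of 0.13 (percentile 76.1), or 0.29 (percentile 94.8) at 2000 UMIs, with 2 of 14 genes at least 2-fold higher, the calcium release channels Ryr2 (9.08 against 3.10 CPM) and Itpr2 (350 against 165). The pump regulator gene Pln, with too few UMIs for that count, was at 1.35 against 0.33 CPM. Atp2a2, the SERCA2 calcium pump (chromosome 5, 122453513 to 122502225), had a log2 ratio of 0.49 (0.45 to 0.54). The triglyceride list had a median of 0.02 (percentile 20.7), with Gk and the glycerol channel gene Aqp7 (1.08) at least 2-fold higher and Dgat1, which makes triglyceride, at -1.07 (-1.11 to -1.04). Its lipase Pnpla2 was at -0.30 (-0.37 to -0.24) and Dgat2 at -0.25 (-0.27 to -0.23).

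Integrated stress genes were lower in CE4 as well, with a median of -0.87 (percentile 0.09) for the list and 4 of 12 members at least 2-fold lower, among them the serine synthesis enzymes Psat1 (-1.40, -1.57 to -1.23) and Phgdh (-1.24, -1.42 to -1.06) and the unfolded protein factor Xbp1 (-1.16, -1.25 to -1.07). Immediate early and heat shock genes had a median of -0.66 (percentile 2.15), which was -0.14 at 2000 UMIs and inside the range of random lists (percentile 32.95), with Junb at -1.55 (-1.74 to -1.37). Branched-chain amino acid catabolism had a median of 0.10 (percentile 53.8), with Bcat1 alone at least 2-fold higher (1.48, 1.25 to 1.73), and beta-adrenergic signalling one of 0.16 (percentile 80.5) with 0 members 2-fold apart. Other genes high in CE4 were Cabcoco1, Kng2, Lgr6 (log2 ratio 3.91 at 2000 UMIs) and Perm1, at 22.5, 26.4, 17.4 and 3.44 CPM against 0.69, 1.06, 0.77 and 0.04 in RT, where Perm1 had 1 UMI (log2 interval 3.91 to 11.7). The lowest were Ier5 (-3.70), the collagen gene Col1a1 (-3.38), Gtf2a1l (-3.29), Wfikkn1 (-3.04), Krt7 (-2.98), Myo3a (-2.93), Pi16 (-2.83) and Adam15 (-2.67), and Col1a1 and Pi16, markers of fibroblast-like progenitors, came to -2.63 and -2.13 at 2000 UMIs.

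As a description of the summed libraries only, 599 genes were at least 2-fold higher and 988 lower in CE4 than in RT, of 11467 with enough UMIs. This compares those libraries, not the conditions, and at 2000 UMIs the numbers were 647 and 652, with Dgat1 (-0.82), Thrsp (-0.78), Slc2a4 (-0.89), Junb (-0.94) and Aqp7 (0.98) no longer 2-fold apart and Perm1, then at 0 UMIs in RT, at least 11.7-fold higher.

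After 7 days in the cold most of the same groups of genes stood on the same side of RT, with smaller ratios for the thermogenic and oxidation lists. Ucp1 was at 32.5 CPM against 4.32 in RT, 7.51-fold higher, with a log2 ratio of 2.91 (2.63 to 3.20). Gk was 11.2-fold higher (407 against 36.5 CPM) and Slc4a4 14.5-fold higher (1036 against 71.6). Dio2, which activates thyroid hormone inside the cell, was at 15.9 against 1.75 CPM, Fabp3 at 6.69 against 0.20 and the secreted factor gene Bmp8b at 2.69 against 0.33.

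Thermogenic genes had a median log2 ratio of 1.36 (percentile 100), with 16 of 23 at least 2-fold higher and 0 lower. Fatty acid oxidation had a median of 0.67 (counting interval 0.32 to 0.70, percentile 100) with 2 of 17 at least 2-fold higher, Acaa2 (1.31) and Etfdh (1.30, 1.21 to 1.39). That median was 0.32 with at most 1% mitochondrial UMIs and 0.46 without doublet removal. Oxidative phosphorylation had a median of 0.52 (percentile 100) with 3 of 23 higher, among them Cox7a1 (3.03, 2.13 to 4.11) and Cox8b (1.41, 1.11 to 1.72, or 2.08 at 2000 UMIs), and with the droplet peak removed Cox7a1 came to 1.92. The glucose list had a median of 0.29 (percentile 99.5), with Ldhb at 2.23 (1.99 to 2.47) and Pdk4 at 1.44 (1.32 to 1.56), and that median was 0.12 at 2000 UMIs and inside the range of random lists (percentile 86.35). De novo lipogenesis had a median of -0.35 (percentile 0.06) with 2 of 16 members at least 2-fold lower, Srebf1 (-1.26, -1.29 to -1.23) and Slc25a1 (-1.23). Its median was -0.18 (percentile 1.24) at 2000 UMIs and, with the droplet peak removed as well, -0.11 (percentile 5.34), inside the range of random lists (-0.15 to 0.25). Fasn was at -0.93 (-0.95 to -0.91), and Acaca at -0.06 (-0.07 to -0.06), which turned to 0.05 with median-of-ratios size factors.

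White adipocyte genes had a median of -0.44 (percentile 0.18) and 3 of 13 at least 2-fold lower, namely Nnat (-2.11), Slc7a10 (-1.55, -1.58 to -1.51) and the natriuretic peptide clearance receptor gene Npr3 (-1.27, -1.32 to -1.23), with Lep at -0.57 (-0.63 to -0.51) and Adipoq at -0.73 (-0.79 to -0.67). Creatine cycling had a median of -0.34 (percentile 51.02) that turned to 0.30 at 2000 UMIs, where Alpl moved from -1.35 to -0.29, Slc6a8 from 1.34 to 0.89 and Ckb from -1.70 to -1.08. Calcium cycling had a median of 0.06 (percentile 73.1), or 0.21 (percentile 91.1) at 2000 UMIs, with Pln (2.42, 1.40 to 3.66, from 8 UMIs in RT) the 1 member at least 2-fold higher. Atp2a2 was at 0.34 (0.30 to 0.38) and Ryr2 at 0.32 (-0.05 to 0.70). The triglyceride list had a median of -0.20 (percentile 0.71). Gk was higher and Lipe, the hormone-sensitive lipase gene, lower (-1.04, -1.06 to -1.02), while Dgat1 was at -0.97, Pnpla2 at -0.36 (-0.43 to -0.30) and Dgat2 at 0.02 (-0.01 to 0.04).

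Integrated stress genes had a median of -0.98 (percentile 0.02) with 5 of 12 at least 2-fold lower, including Phgdh (-1.65, -1.84 to -1.46), Shmt2 (-1.31, -1.64 to -0.97) and Xbp1 (-1.19, -1.28 to -1.10). Immediate early genes had a median of -0.60 (percentile 7.72), with Junb at -2.45 (-2.67 to -2.24) and Jun at -1.26 (-1.46 to -1.06), and at 2000 UMIs that median was -0.36 (percentile 18.4) and Junb at -1.81. The beta-adrenergic list had a median of -0.03 (percentile 38.9) over members that went both ways. Its receptor gene Adrb3 was at -1.06 (-1.11 to -1.01), adenylate cyclase Adcy5 at -1.35 (-1.44 to -1.26) and the kinase subunit Prkar2b at 1.06 (1.04 to 1.08). Branched-chain catabolism had a median of -0.03 (percentile 34.4), with Bcat1 at 1.03 (0.79 to 1.27). Among the highest genes were also Lgr6 (4.47), Kng2 (4.35), Cabcoco1 (4.06), Perm1 (5.61, 3.11 to 10.9) and Cyp2b10 (4.47), and the lowest were Emp1 (-3.69), Mest (-3.46), Pi16 (-3.06), Flna (-3.04), the complement gene Cfb (-3.03), Id3 (-3.00), Ier5 (-2.84) and Plppr3 (-2.80). At 2000 UMIs Cyp2b10 came to 3.43, Lgr6 to 3.79 and Pi16 to -2.44. Perm1, then at 0 UMIs in RT, was at least 6.42-fold higher.

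In the summed libraries 395 genes were at least 2-fold higher and 1103 lower in CE7 than in RT, of 11429 with enough UMIs, a share of higher genes of 26.4%. Median-of-ratios size factors moved the median log2 ratio of all genes from -0.06 to 0.06 and that share to 36.6%, and at 2000 UMIs, where Lipe (-0.87), Adrb3 (-0.94), Bcat1 (0.87), Shmt2 (-0.98) and Slc25a1 (-0.99) were no longer 2-fold apart, 450 genes were higher and 761 lower.

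**Figure D2:**
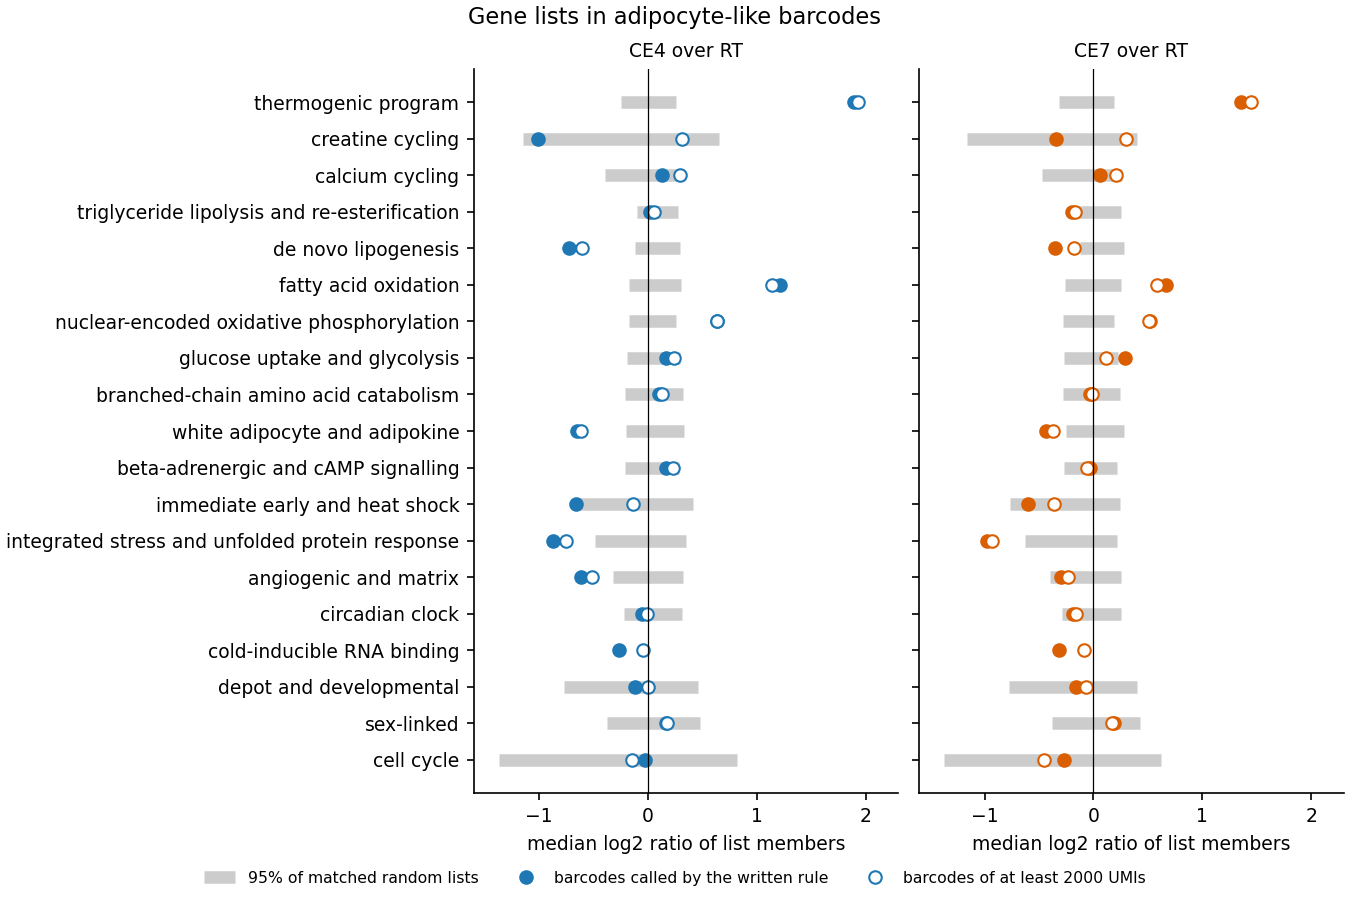
Median log2 ratio (horizontal axis) of each of 19 gene lists (vertical axis) for CE4 over RT (left) and CE7 over RT (right). Filled points are barcodes above the UMI minimum of each library, open points barcodes of at least 2000 UMIs and grey bars the middle 95% of matched random lists, and the thermogenic list stands at 1.89 and 1.36 while creatine cycling moves from -1.01 to 0.31 and from -0.34 to 0.30.

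Between the 2 cold libraries, thermogenic and oxidation genes were lower after 7 days than after 4. Ucp1 was at 32.5 against 161 CPM, 4.95-fold lower in CE7, with a log2 ratio of -2.31 (-2.37 to -2.24), and Cox7a1 was 4.68-fold lower. The ferritin gene Fth1 (-2.13, -2.23 to -2.03), the matrix gene Adamtsl3 (-2.88, -3.20 to -2.56) and Olfr66 (-2.30, -2.74 to -1.88) were the other lowest genes. The highest in CE7 were Cfd (331 against 99.2 CPM), the haemoglobin gene Hbb-bt (2.08, 1.68 to 2.50), Tead4 (1.90, 1.67 to 2.12), the clock gene Npas2 (1.97, 1.67 to 2.27) and Mup22 (2.35, 1.66 to 3.12). Cfd and the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs were among the leading genes of the haemoglobin and mitochondrial cluster. Of the 6910 barcodes in that cluster, 6283 were from CE7. Free RNA in CE7 may thus be part of the Cfd and Hbb-bt differences, which was not tested.

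The thermogenic list had a median of -0.39 (percentile 0.00) for CE7 over CE4 with 3 of 23 members at least 2-fold lower, fatty acid oxidation one of -0.53 (percentile 0.00) with 2 of 17 lower, de novo lipogenesis one of 0.12 (percentile 99.6) and white adipocyte genes one of 0.12 (percentile 99.9). The creatine, calcium and triglyceride lists had medians of -0.06, 0.00 and -0.09. In these summed libraries 49 genes were at least 2-fold higher and 119 lower, of 11591, and median-of-ratios size factors gave 70 and 92, moving the share of higher genes from 29.2% to 43.2%.

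The cold libraries shared many of their differences from RT. Of 11283 genes with enough UMIs for both, 312 were at least 2-fold higher in both CE4 and CE7 and 799 lower in both, with 0 in opposite directions. Independent lists of these lengths would share 18.1 and 93.8 genes. Libraries simulated with no difference from the same RT library shared 0.14 and 0, with a correlation of log2 ratios across genes of 0.759 and a covariance of 0.0099, beside 0.916 and 0.439 in the data. The simulation held counting error only. Both comparisons used the same RT library, and anything that set it apart from both cold ones would give shared genes. The excess therefore cannot be credited to the cold. At 2000 UMIs 347 and 472 genes were shared.

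Ucp1 molecules were found in few adipocyte-like barcodes at equal depth. After thinning to 1000 UMIs, at least 1 Ucp1 UMI was present in 0.42% of RT barcodes (0.29 to 0.59), 11.85% of CE4 (11.35 to 12.36) and 3.12% of CE7 (2.87 to 3.39), with 14910 shallower RT barcodes and 0 cold ones left out. The unthinned shares were 0.40%, 29.4% and 9.78%, at median depths of 699, 3869 and 3668 UMIs. Macrophage, progenitor and endothelial barcodes, which should lack Ucp1, held it in 0 of 152 in RT (0 to 2.40%), 7.25% in CE4 (4.74 to 10.5) and 1.94% in CE7 (0.71 to 4.16) at the same thinned depth, from median depths of 1205, 2757 and 2831 UMIs. The RT share lies inside the interval of its background and the CE7 interval overlaps that of its background, so from these shares neither can be told from free RNA, and in CE4 alone adipocyte-like barcodes stood above it. That separation was lost at 500 UMIs (6.27%, 5.90 to 6.66, against 3.77%, 2.02 to 6.36) and with at most 1% mitochondrial UMIs (11.70%, 11.17 to 12.24, against 8.28%, 4.35 to 14.01), where the intervals overlap. At 500 UMIs the droplets of the peak held Ucp1 in 10.0% in CE4 and 2.31% in CE7, against 6.27% and 1.42% of adipocyte-like barcodes. In these libraries a single Ucp1 UMI thus does not mark a nucleus that makes it. The RT values were 0.18% and 0.19%, but the RT droplets measured there had 500 to 562 UMIs and so reached the RT calling minimum. Called barcodes were not taken out of these droplets. The RT sets therefore overlap and their match shows nothing about free RNA, and the CE7 sets overlap in part. The droplets of the peak held Ucp1 at 210 CPM in CE4 and 46.7 in CE7, more than the 161 and 32.5 of adipocyte-like barcodes. With at least 2 Ucp1 UMIs at 1000, the CE4 share was 2.40% (2.17 to 2.65) in adipocyte-like barcodes and 0.87% (0.18 to 2.52) in the other classes, and the CE7 share was 0.19% (0.13 to 0.27) against 0 of 310 (0 to 1.18%). Neither lies clear of that background, though in barcodes of at least 2000 UMIs the CE4 share does, at 2.64% (2.39 to 2.91) against 0.38% (0.01 to 2.08).

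Within each cold library, Ucp1-high nuclei were set against Ucp1-negative ones to ask whether futile-cycle genes go with Ucp1 from nucleus to nucleus. In another random thinning to 1000 UMIs than the one behind those shares, CE4 had 405 Ucp1-high and 14099 Ucp1-negative nuclei and CE7 had 39 and 17201, while RT, with 3, gave no comparison. Ucp1-high nuclei of both libraries held more RNA of Slc4a4 (log2 ratio 1.84, 1.75 to 1.92 in CE4 and 1.61, 1.33 to 1.88 in CE7), Gk (1.57, 1.40 to 1.74 and 1.81, 1.39 to 2.19), the cytoskeletal gene Sept9 (1.49 and 2.16), the mitochondrial carrier gene Slc25a42 (1.38 and 1.79) and the coactivator gene Ppargc1b (1.36 and 1.32). They held less of Cyp2e1 (-2.49, -3.56 to -1.61 in CE4), Eepd1 (-2.12), Abi3bp (-2.08), Slc2a3 (-2.05) and Rbms3 (-2.04), which in CE7 rest on 1 or 2 UMIs in the Ucp1-high nuclei, and in CE4 barcodes of at least 2000 UMIs Cyp2e1 came to -1.10 and Rbms3 to -3.12. These higher and lower genes were picked as extremes with the same direction in both libraries, so their agreement between CE4 and CE7 is not a replication. A control chosen after seeing the data set barcodes with at least 1 Ucp1 UMI against those without at 500 UMIs. Slc4a4 was then at 1.37 (1.28 to 1.46) in adipocyte-like barcodes of CE4 and 1.36 (1.21 to 1.52) in those of CE7, but at -0.01 (-0.09 to 0.06) and -0.06 (-0.25 to 0.13) in the droplets of the peak. Likewise Gk was at 1.27 (1.10 to 1.43) and 1.63 (1.40 to 1.85) against -0.05 (-0.18 to 0.07) and -0.11 (-0.37 to 0.15).

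The thermogenic list without Ucp1 had a median of 1.36 in CE4 and 1.07 in CE7, fatty acid oxidation 0.74 and 0.85, oxidative phosphorylation 0.54 and 0.67, de novo lipogenesis -0.27 and -0.47 and white adipocyte genes -1.64 and -0.92. Calcium cycling had medians of 0.54 (percentile 99.88 among random lists drawn after seeing the data) over 8 genes in CE4, of which 4 had intervals above 0 and 2 below, and 0.75 (percentile 99.95) over 6 in CE7, with 3 above and 0 below. At 500 UMIs, with at least 1 Ucp1 UMI against none, the calcium medians were smaller, at 0.31 in adipocyte-like barcodes of CE4 and 0.28 in those of CE7. In the droplets of the peak, at that same setting, the calcium list was at 0.01 and -0.05. Oxidative phosphorylation was at 0.10 (percentile 99.96) in the droplets of CE4 and -0.01 in those of CE7, beside 0.47 and 0.34 in adipocyte-like barcodes. In Ucp1-high nuclei of CE4 at 1000 UMIs, the release channels Itpr2 (1.01) and Itpr1 (0.78, 0.66 to 0.91), the pump Atp2a2 (0.58, 0.36 to 0.81) and the sensor Stim1 (0.50, 0.35 to 0.65) were higher. The kinase Camk2d (-0.44, -0.64 to -0.25) and Stim2 (-0.75, -1.28 to -0.26) were lower. Atp2a2 was not clear of 0 in CE7 (0.71, -0.07 to 1.39), nor at 500 UMIs in CE4 (0.21, -0.03 to 0.43) or CE7 (0.26, -0.19 to 0.68). Itpr1, Itpr2 and Stim1 were above 0 in each of these. Camk2d was not clear of 0 in CE7 (-0.54, -1.25 to 0.09). The triglyceride list had no direction, with medians of -0.06 (-0.12 to 0.08) and 0.04 (-0.27 to 0.22). Within it Gk, Agpat3 (0.68, 0.28 to 1.05 in CE4), Gpam (0.52, 0.33 to 0.70) and Gpat4 (0.44, 0.11 to 0.75) were higher in Ucp1-high nuclei of CE4, and Gpat3 (-1.66, -2.31 to -1.09), Dgat2 (-0.68, -0.90 to -0.46) and Slc27a1 (-0.48, -0.62 to -0.33) lower. No creatine gene had enough molecules at this setting. Alpl had 6 UMIs in the Ucp1-high nuclei of CE4 and 83 in the Ucp1-negative ones, a log2 ratio of 1.33 whose interval ran from -0.15 to 2.52. Ucp1-high nuclei were also deeper before thinning, with median UMIs of 4780 against 3843 in CE4 and 4241 against 3664 in CE7. With a minimum of 1 Ucp1 UMI the calcium median in CE4 was 0.23. At that minimum 1 creatine gene was measured in each cold library. It was at 1.07 in CE4, with an interval above 0, and at 0.06 in CE7, with an interval not clear of 0. Thinned to 2000 UMIs, with at least 2 Ucp1 UMIs, 1 was measured in CE4, at 0.45 and not clear of 0.

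**Figure D3:**
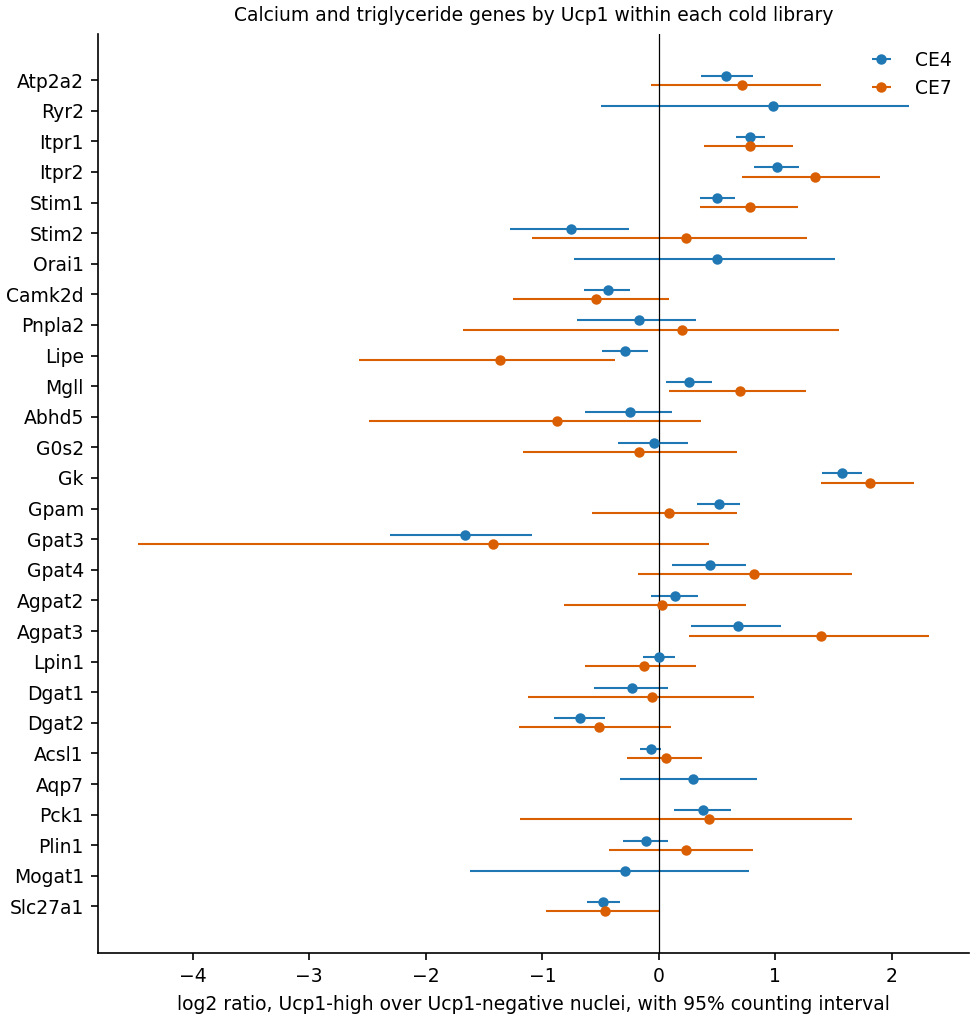
Log2 ratio of Ucp1-high over Ucp1-negative nuclei (horizontal axis) for calcium and triglyceride genes (vertical axis) in CE4 and CE7, thinned to 1000 UMIs, with 95% counting intervals as bars and genes shown only where enough UMIs allow. Gk stands at 1.57 and 1.81, Itpr1, Itpr2 and Stim1 lie above 0 in both libraries, and Gpat3, Dgat2 and Slc27a1 lie below 0 in CE4.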

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

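Every test in this part was chosen after the result was seen.

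Among the genes named for the comparisons between libraries, 4 had counting intervals wholly on opposite sides of 0 in the 2 cold libraries, and the difference was not tested. Adamtsl3 was at 0.63 in CE4 and -2.25 in CE7 over RT, and the haemoglobin gene Hbb-bt at -1.22 and 0.86, where at 2000 UMIs its CE4 ratio was -0.43 (-1.31 to 0.55) and no longer clear of 0, and its CE7 ratio 1.58. The clock gene Npas2 was at -1.47 and 0.49, and Tead4, a partner of the YAP coactivator, at -0.48 and 1.42.

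Barcodes too shallow to be called, which the comparisons above do not use, were shared between libraries. Of barcodes with 51 to 200 UMIs, 97.89% in RT, 98.25% in CE4 and 98.52% in CE7 held at least 1000 UMIs in another library, where 1.088%, 0.924% and 0.531% would do so by chance. At the median, RT ones held 1.19% and 1.17% of the UMIs of the same barcode in CE4 and CE7, CE4 ones 1.03% of those in CE7, and CE4 and CE7 ones 3.43% and 3.81% of those in RT. The CE7 ones had Ucp1 at 168 CPM where shared with CE4 and 4.90 where not, which is consistent with molecules passed between libraries.

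Ucp1 was higher in both cold libraries, and 3 technical explanations were weighed. If free RNA in the amount of 1 droplet per barcode carried the difference, removing the droplet peak should have brought the smaller log2 ratio near 0. It stayed at 2.47, with 5.02 for the other, so that amount does not account for the difference. That amount held only 13.2% of the Ucp1 UMIs in RT, 21.1% in CE4 and 36.4% in CE7, so its removal could not move the ratios far. The droplets of the peak differed as well, with Ucp1 at 3.91 CPM in RT, 210 in CE4 and 46.7 in CE7. Free RNA in a larger amount is therefore left open. If depth did, deep RT barcodes should hold as much Ucp1 as deep CE4 ones, but barcodes above 4000 and up to 8000 UMIs had 2.17 CPM in RT (5 UMIs, upper limit 5.06) and 164 in CE4. A larger part of brown-depot nuclei could not be told, since of the brown-depot markers only Lhx8 had enough UMIs, with a log2 ratio of -0.17 (-0.41 to 0.08). Cold exposure itself was not tested apart from the library, because the 2 are the same here.

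More genes were at least 2-fold lower than higher in the cold libraries, which may come from droplets without a nucleus among the RT barcodes. With a minimum of 2000 UMIs and the droplet peak removed, 45.9% of 2-fold genes (43.1 to 48.8) were lower in CE4, against 62.3% before, so no majority was left. That minimum also cut the summed RT UMIs from 24524140 to 10281277, and with the peak removed the genes with enough UMIs went from 11467 to 11013. The shift is thus not set apart from the loss of depth in RT. In CE7 57.5% (54.4 to 60.5) were still lower, against 73.6% before. Median-of-ratios size factors alone left 60.2% (57.8 to 62.7) lower in CE4 and 63.4% (60.7 to 65.9) in CE7, and both changes together left 48.2% (45.1 to 51.4) in CE7. Because such factors shift all genes of a library alike, the balance in CE7 depends on where the ratios are centred and its explanation is left open, and cold exposure was not tested apart from the library.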

How the results depend on the processing

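Of the results that answer a comparison, 213 values stayed within their limits under an alternative, 68 moved and 6 changed sign. Among single named genes and other values, 1419 stayed, 485 moved and 9 changed sign. A change of sign was counted only where the counting interval of the value first given lay clear of 0. Every Ucp1 ratio over RT stayed above 0. No paired analysis was possible because each group has 1 library and no result comes from a test. The cause was not tested unless named. Depth limits RT most, where few barcodes reach 2000 UMIs and the rarest genes rest on few molecules.

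With 10% free RNA removed, the Ucp1 log2 ratio was 10.27 in CE4 and 7.82 in CE7 over RT, which are not read as Ucp1 ratios. RT barcodes of 11 to 50 UMIs, part of the removed profile, held Ucp1 at 73.4 CPM against 4.32 in adipocyte-like ones, and 64.73% of them held at least 1000 UMIs in another library, so molecules swapped between libraries are not excluded. The thermogenic medians were 2.04 and 1.52, and 85 genes were higher in CE7 over CE4.

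With at least 2000 UMIs, 3399 RT barcodes were kept, adipocyte-like shares were 98.23%, 98.25% and 98.86%, the creatine medians 0.31 and 0.30 and the triglyceride median in CE4 0.05, and 652 genes were lower in CE4 and 472 in both. With the droplet peak removed as well, an alternative chosen after seeing the data, Ucp1 in CE7 was at 2.47, lower genes numbered 561, 611 and 387 in both, and medians were 1.98 for the thermogenic list in CE4, 0.62 and 0.46 for creatine, and 0.02 (CE4 over RT) and 0.03 (CE7 over CE4) for the clock. Adding median-of-ratios size factors, also chosen after seeing the data, gave 2.54 for Ucp1 and 0.01 for Acaca in CE7, 592 and 488 lower genes, 83 genes higher in CE7 over CE4, thermogenic medians of 1.97 and 1.51 and creatine ones of 0.60 and 0.53. In CE7 the calcium median was then 0.28 and the triglyceride one -0.08, and for CE7 over CE4 branched-chain catabolism was at 0.04 and the clock at 0.11.

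Median-of-ratios size factors alone gave 0.05 for Acaca in CE7, triglyceride medians of 0.05 and -0.08, a thermogenic median of 1.48 in CE7, and 0.01, 0.05 and 0.06 for oxidative phosphorylation, branched-chain catabolism and the clock in CE7 over CE4. The mean of per-barcode values gave triglyceride medians of 0.08 and -0.10. A count minimum of 300 left 390 genes higher and 644 lower in CE4, 250 and 720 in CE7, 76 lower in CE7 over CE4, and 189 and 511 shared, because fewer genes were tested. A minimum of 30 gave 1494 lower in CE4, 105 higher and 203 lower in CE7 over CE4, and 481 shared higher, because more were.

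With at least 500 UMIs, 30316 CE4 barcodes were kept, adipocyte-like shares were 97.17%, 36.55% and 37.32%, 12.58% of CE4 barcodes held Ucp1, the thermogenic median in CE4 was 1.98 and the triglyceride median of Ucp1-high nuclei in CE7 -0.33. With at most 1% mitochondrial UMIs, 11674 RT barcodes were kept, the shares were 98.34%, 98.59% and 83.19%, 0.60% of RT barcodes held Ucp1 and that triglyceride median was -0.31. Without doublet removal the shares were 93.55% in CE4 and 53.68% in CE7. Resolution 1.0 gave a Ucp1 share of 2.74% in CE7 and a triglyceride median of -0.14 in Ucp1-high nuclei of CE4.

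Thinned to 500 UMIs, Ucp1 was found in 0.19%, 6.27% and 1.42% of RT, CE4 and CE7 barcodes, and thinned to 2000 in 0.94%, 19.60% and 5.45%, because depth sets the chance of finding a molecule. At least 2 Ucp1 UMIs were found in 0.03%, 2.40% and 0.19%. With 1 Ucp1 UMI as the minimum, the calcium median of Ucp1-high nuclei in CE4 was 0.23.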

Other observations

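The test in this part was chosen after the result was seen, and the lists below were fixed before the data were examined.

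Matrix and blood vessel genes were lower in CE4 than in RT, with a median log2 ratio of -0.62 (percentile 0.17). Of 15 members, 3 were at least 2-fold lower and 1 higher. In CE7 the median was -0.30 (percentile 6.03), inside the range of random lists (-0.40 to 0.25), with 4 lower and 2 higher. At 2000 UMIs the CE4 median was -0.52, with Col6a1 at -2.37 and Col6a3 at -2.34. Only 1 of 15 members was then counted as at least 2-fold lower, a count that needs at least 100 UMIs in either library. The progenitor markers Col1a1 (-3.38) and Pi16 (-2.83) were lower in CE4 along with this list. The collagen VI genes Col6a1 and Col6a3 were at -2.46 and -2.26 in CE4 and -1.84 and -1.61 in CE7. The vessel growth factor gene Vegfa, named after its values were seen, was at 714 CPM in CE4 and 708 in CE7 against 1477 in RT. Angpt2, which loosens vessel walls, was higher, at 2.21 (1.69 to 2.76) and 1.95 (1.44 to 2.51). Between the cold libraries the list was higher in CE7, at 0.30 (percentile 100).

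Circadian clock genes had medians of -0.06 (percentile 15.6) in CE4 and -0.19 (percentile 8.37) in CE7. Ciart, a repressor in the clock, was at 2.21 (2.03 to 2.39) and 1.47 (1.29 to 1.66), and the activator Arntl at -1.80 (-1.88 to -1.71) and -1.23 (-1.31 to -1.15). The cold-inducible RNA-binding genes had medians of -0.27 and -0.32, with Cirbp at -0.59 and -0.98 and Rbm3 at 0.04 and 0.35. Depot and developmental genes had medians of -0.12 (percentile 40.0) and -0.16 (percentile 39.8), with Epsti1 at -1.77 and -1.52, which came to -1.04 and -0.82 at 2000 UMIs. Sex-linked genes had medians of 0.16 and 0.19, and the Y-chromosome genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in every library, with Uty at 611, 728 and 753 CPM. Cell cycle genes had medians of -0.03 and -0.27. For CE7 over CE4 the clock list stood at -0.03, oxidative phosphorylation at -0.08, glucose at 0.04, branched-chain catabolism at -0.04, beta-adrenergic signalling at -0.14, immediate early genes at -0.07, integrated stress at -0.23, cold-inducible RNA binding at -0.04, depot genes at -0.06, sex-linked genes at 0.04 and cell cycle genes at -0.28.

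The clock genes raise the hypothesis that the libraries were collected at different clock phases. The median log2 ratio of 7 clock output genes minus that of 4 activator-phase genes was 1.23 in CE4, with 4 of 4 activators lower and 5 of 7 outputs higher, which restates the differences that prompted it and so leaves the phase open. In CE7 it was -0.48, with 1 activator lower and 2 higher and 3 outputs higher and 4 lower, which cannot tell. No biological explanation was tested for it.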
